A study of Mus musculus with 16 samples.

How the data were processed

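Kidney RNA of 16 mice was measured by sequencing of polyadenylated RNA, 4 animals in each of 4 groups formed by sex and Klotho genotype. The labels gave the group, genotype, age and library name of each animal. The authors deposited 1 table of TPM, a length-scaled expression value, with 30277 genes after a Kl entry listed again with identical values was counted once. Per the submitters' processing notes the software was Partek and the genome build mm39. The aligner, the counting rule, the annotation release and any filter are not given in the sources used here. Each column matched 1 library by name, and 0 columns of other samples were found.

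The deposited TPM sum to about 309450 in every library, far below the total the unit's name implies. Tested on the values, they follow reads plus 0.0001, divided by the length of the gene from start to end, introns included, and scaled to that total. A gene with long introns therefore gets a small TPM, and intronless pseudogenes and mitochondrial genes get large ones. The length of a gene is the same in every library and cancels in the ratio of its own TPM before scaling. It still enters a comparison through the fixed total, of which mitochondrial genes held 30.7% to 47.5% (9.72% to 19.6% of reads) and pseudogenes 30.4% to 37.9% (6.21% to 9.92% of reads). It also enters through the pseudocount of 1, which shrinks the differences of genes with long introns, and the filter on TPM favours short genes. Reads were recovered from these relations, so the read-based values rest on that inference. Of low values (under 20 reads) 81.0% came out whole within 0.1 reads. A count of 0 allows up to 3 reads, which for a gene of 1 kb is 0.136 to 0.25 TPM, for counting error only. Recovered depth ranged from 8209808 to 20106723 reads.

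Genes with a TPM of 1 or more in at least 4 of the 16 libraries were tested, 8059 in all. Values were log2(TPM + 1), so that differences of low genes are understated. Limma 3.58.1 in R 4.3.3 fitted a mean for each group over all libraries (12 residual degrees of freedom) with a mean-variance trend in the moderated test. Every adjusted p of a gene is limma's, by the Benjamini-Hochberg method within a contrast, with a threshold of 0.05. The 5 contrasts were KlKl against control in males and in females, the difference of these effects, and males against females in controls and in KlKl. Heterozygous and wild-type animals formed 1 control group because both were described as healthy.

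Gene lists, 23 of pathways and 16 of cell types, were fixed before the data were examined. The 32 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation and with the rotation test fry. Of 596 listed genes 6 were matched under an older symbol and 10 had no match. The comparisons, tests, lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule names Kl in every comparison and, per contrast and direction, the 10 genes with the largest difference among those that pass, have a mean TPM of at least 5 and do not overlap between the groups. Chance gives no overlap for 2 of 70 arrangements of 4 against 4 libraries. Unnamed gene models, pseudogenes and genes without a symbol were left out. The rule adds up to 4 passing members of each list, members that do not pass where their value is given, and Xist and the Y-linked genes as a check of labels.

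The fit was tested on simulated data, with 200 genes changed by known amounts in the male renal failure comparison. Of genes changed by 0.5, 1 and 2 on the log2 scale it recovered 44.8%, 89.6% and 97%, with 5 false calls among 7859 unchanged genes. In the female comparison it recovered 49.3%, 92.5% and 98.5%. The read-based fit recovered 16.4%, 67.2% and 77.3% in males over 17648 genes. Of 200 unchanged random lists 4 had a camera p under 0.05. In those simulations genes varied independently, unlike in the libraries. With 200 genes changed at once the adjusted threshold is also easier to pass than where few genes change. The shares recovered therefore do not give the power of a comparison in which few genes passed.

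Alternatives covered the pseudocount, the filter, the scaling of the libraries, the moderated test, weights for libraries, covariates for age, name series and replicate number, heterozygous controls alone, the libraries of a contrast alone, stricter thresholds and leaving out each library in turn. Chosen after seeing the data were limma voom on recovered reads (genes with 10 reads or more in at least 4 libraries, 17648 genes), scaling on nuclear protein-coding genes, leaving out female control 3 and male KlKl 3 together, age on median-ratio scaled values or without female control 3, weights on median-ratio scaled values, and the mean effect of both sexes. Replicates of a group differed by more than counting error, with chi-square values per degree of freedom of 6.8 to 128.5 over genes, so no library was counted as a copy of another.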

Results

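The data are polyadenylated RNA profiles of whole kidneys from 16 C57BL/6J mice in 4 groups of 4 animals, each library from its own animal. Klotho, the gene Kl, encodes a kidney membrane protein that acts as co-receptor for the phosphate-regulating hormone FGF23. Mice homozygous for the recessive Kl allele, called KlKl here, had renal failure per the labels, and the controls, with at least 1 normal allele, had healthy kidneys. The groups were male control, male KlKl, female control and female KlKl, at ages of 46 to 59 days. Male controls 1 and 2 and the 4 female controls were heterozygous, and male controls 3 and 4 were wild type. The reads recovered from the deposited values numbered 13028292 to 20106723 per male library and 8209808 to 14504114 per female library. Mitochondrially encoded genes held 30.7% to 47.5% of the TPM of a library and pseudogenes 30.4% to 37.9%. Ribosomal RNA held 15.2% of the TPM of female control 3, the library with the fewest reads, and 3.32% to 6.18% of the other libraries.

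Kl itself followed the genotype labels in every library. The gene lies on chromosome 5 at positions 150876072 to 150917283, plus strand, build mm39, with the identifier ENSMUSG00000058488. Its TPM was 10.2 ± 1.7 in male controls, 0.943 ± 0.52 in male KlKl, 3.39 ± 1.7 in female controls and 0.142 ± 0.079 in female KlKl (SD, n = 4 each). The lowest control of each sex, male control 2 at 7.82 and female control 4 at 2.04, lay above the highest KlKl library of its sex, at 1.49 and 0.222. The wild-type male controls stood at 11.7 and 10.97 and the heterozygous males at 10.2 and 7.82. The sex labels were checked with Xist, the RNA that silences an X chromosome, which averaged 12.9 and 13.9 TPM in female control and KlKl kidneys against 0.103 and 0.367 in the males. The Y-linked genes Ddx3y and Eif2s3y averaged 2.3 and 2.28 TPM in male controls and 3.01 and 2.83 in male KlKl, and at most 0.00602 TPM in either female group. 2 members of the Y-linked list were measured above the filter, too few for a list test.

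The first comparison asked what renal failure changes in the male kidney. Kl fell by 2.55 on the log2(TPM + 1) scale (SE 0.23, adjusted p = 6.87e-05), and 7 other genes of 8059 passed. Serpina1a, which encodes an alpha-1 antitrypsin, a protease inhibitor of plasma, rose by 2.13 (SE 0.34, adjusted p = 0.0319), from 4.22 ± 2.15 to 21.3 ± 8.53 TPM (n = 4). Rarres2, which encodes the chemoattractant adipokine chemerin, rose by 2.08 (SE 0.35, adjusted p = 0.0325), from 5.73 ± 1.06 to 30.4 ± 13.5 TPM. The glutathione transferase gene Mgst1 rose by 1.03 (SE 0.14, adjusted p = 0.00711). Serpina1a belongs to a family of near-identical copies, so the split of reads among them is uncertain.

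The other passing genes were small in level. The amino acid transporter gene Slc7a12, a member of the female-biased list, rose by 1.14 (SE 0.20, adjusted p = 0.0439) from 0.252 to 1.79 TPM, next to 1.64 in female controls. Trib1, a pseudokinase gene, rose by 0.66 (adjusted p = 0.0439). The noncoding gene B430119L08Rik rose by 1.13 (adjusted p = 0.0325) and the pseudogene Gm6300 fell by 1.58 (adjusted p = 0.0319). B430119L08Rik lies near Serpina1a on chromosome 12, and Gm6300 near Slc7a12 on chromosome 3. Mgst1, Trib1, B430119L08Rik and Gm6300 lie outside the naming rule and were chosen after their values were seen. In the vitamin D axis, Cyp24a1, the enzyme that inactivates vitamin D hormone, had a log2 difference of 2.67 (SE 0.59, adjusted p = 0.128), and Cyp27b1, the enzyme that makes the hormone, one of 1.58 (SE 0.31, adjusted p = 0.0728). The phosphate and vitamin D list did not pass in males (camera adjusted p = 0.534, median 0.151). Cyp24a1 stood at 49.1 to 76.9 TPM in 3 KlKl males and at 4.48 in male KlKl 3, against 3.01 to 6.2 in the controls.

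Among gene lists, tubule injury and repair genes rose as a group in males (camera adjusted p = 8.17e-06; adjusted p = 0.173 with an estimated correlation). All 9 measured members had positive differences with a median of 0.59, 7 of them passed when adjusted over the list alone and 0 over all genes. Examples are Spp1, which encodes osteopontin, at 1.02 (adjusted p = 0.101), Clu, a secreted chaperone gene, at 0.69 (adjusted p = 0.104), and the intermediate filament gene Vim at 0.59 (adjusted p = 0.104). Mineralisation genes rose (adjusted p = 0.000334; adjusted p = 0.137 with an estimated correlation), 5 of 5 when adjusted over the list alone, and the calcification inhibitor gene Mgp differed by 0.81 (adjusted p = 0.203). Lists of other cell types had positive medians without passing: 0.419 for macrophage and dendritic cell genes (adjusted p = 0.0541), 11 of 11 positive, and 1.971 for erythrocyte genes (adjusted p = 0.141), 4 of 4 positive, with the globin gene Hba-a1 at 2.02 (adjusted p = 0.222). Both had an adjusted p of 0.672 with an estimated correlation, and both passed on reads with voom (adjusted p = 0.012 and 0.000734). Thick ascending limb genes rose (adjusted p = 0.0372; adjusted p = 0.672 with an estimated correlation), 5 of 11 when adjusted over the list alone. Their examples are Umod, which encodes uromodulin, at 0.55 (adjusted p = 0.209), and the salt transporter gene Slc12a1 at 0.54 (adjusted p = 0.209). This call ended without male control 1 (adjusted p = 0.141), male control 4 (0.0646), male KlKl 1 (0.0651), male KlKl 3 (0.0588), male KlKl 4 (0.0625) or female control 3 (0.0513).

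The male-biased list fell in KlKl males (adjusted p = 2.03e-12; adjusted p = 0.0885 with an estimated correlation), with 9 of 10 members negative, a median of -0.427, and 1 passing when adjusted over the list alone. Slco1a1, an organic anion transporter gene, differed by -1.39 (SE 0.30, adjusted p = 0.104). The androgen-regulated gene Kap differed by -1.02 (adjusted p = 0.287), and Odc1, which encodes the first enzyme of polyamine synthesis, by -0.60 (adjusted p = 0.339). Without male KlKl 3 the list median was -0.043 with an adjusted p of 3.64e-05, Kap differed by -0.34 and Odc1 by -0.22, and without male KlKl 1 Odc1 differed by -0.91. Mitochondrially encoded transcripts fell (adjusted p = 3.08e-19; adjusted p = 0.0885 with an estimated correlation), 13 of 13 negative with a median of -0.233, and 0 passed when adjusted over the list alone. Organic ion transporters were lower relative to other genes (adjusted p = 2.77e-10; adjusted p = 0.173 with an estimated correlation), with a median of -0.142 and 1 of 16 lower when adjusted over the list alone. Slc22a7 differed by -1.28 (adjusted p = 0.33), and by -0.35 without male KlKl 3, which stood at 0.589 TPM against 9.4 to 32.4 in the other KlKl males. Cholesterol synthesis genes had a median of -0.04 and were lower relative to other genes (adjusted p = 1.67e-07; adjusted p = 0.173 with an estimated correlation), 1 of 12 when adjusted over the list alone, and Idi1, an isoprenoid enzyme gene, differed by -1.11 (adjusted p = 0.157). Proximal tubule markers were lower relative to other genes (adjusted p = 0.00695; adjusted p = 0.672 with an estimated correlation), 0 of 21 when adjusted over the list alone, although their median was 0.14 and the rotation test fry pointed up (adjusted p = 0.407). This call ended without male KlKl 3 (adjusted p = 0.154). By fry, which tests a list by itself and not against other genes, the injury, mineralisation and thick ascending limb calls of the males were kept, and 0 of the 5 lists called lower. On the deposited scale the median difference over all tested genes was 0.18 in males, which favours higher calls by fry.

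In total 8 genes passed in males, 6 higher and 2 lower, and 1603 of 8059 (19.9%) had an unadjusted p under 0.05, against 1096 of 17648 (6.21%) in limma voom on reads. The median difference over all tested genes was 0.18, and after median-ratio scaling it was -0.005, with 0 genes higher and 2 lower. Limma voom on recovered reads called 5 genes: Kl, Mgst1, Slc7a12, Crabp1 and Osbp2, the first 3 shared with the TPM result and the others chosen after their values were seen. Kl passed without each of the 16 libraries in turn and after each scaling tried, and Mgst1 without each library but not after median-ratio scaling (adjusted p = 0.103). The call ended without 7 of the 16 libraries for Serpina1a and B430119L08Rik, 8 for Gm6300, 10 for Rarres2, 13 for Slc7a12 and 14 for Trib1, with the log2 difference in the same direction each time and an adjusted p of 0.0501 to 0.164 where it ended. With age as a covariate 909 genes passed, 904 of them higher, and with age on median-ratio scaled values 1 passed. Male KlKl 4 was 59 days old against 46 to 49 in the other males, so among males age is hardly separated from that animal. Female control 3 was 57 days old against 47 to 52 in the other females, and without it the count with age was 1674. The count was 2 without male control 1, 2 or 3 or female control 2, 3 without female control 4, 4 without male KlKl 1 or female KlKl 4, 5 without male control 4 or female KlKl 3, and 17 without female control 3.

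**Figure D1:**
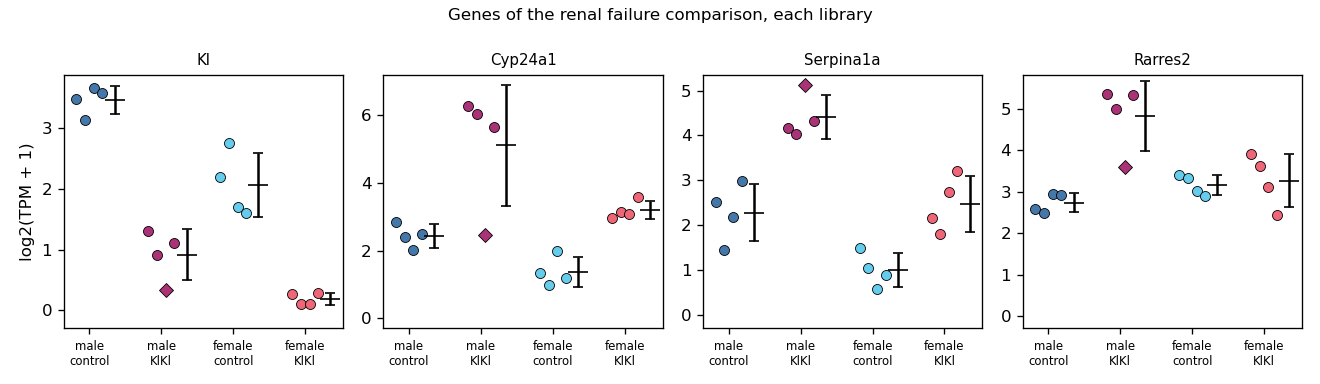
Levels of Kl, Cyp24a1, Serpina1a and Rarres2 as log2(TPM + 1) in each of the 16 libraries, by group, with the mean and SD of each group of 4 in black and male KlKl 3 as a diamond. Kl is lower in both KlKl groups, and Cyp24a1 stood at 4.48 TPM in male KlKl 3 against 49.1 to 76.9 TPM in the other KlKl males.

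The same question in females gave Kl as the passing gene. It fell by 1.87 (SE 0.23, adjusted p = 0.00448), from 3.39 ± 1.7 to 0.142 ± 0.079 TPM (n = 4). Serpina1a differed by 1.48 (SE 0.34, adjusted p = 0.727), with 1.06 ± 0.56 TPM in controls and 4.98 ± 2.57 in KlKl females. Cyp24a1 differed by 1.82 (SE 0.59) and Cyp27b1 by 0.81 (SE 0.31), both with an adjusted p of 0.727. Spp1 differed by 0.37 and Clu by 0.45, also at 0.727.

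Macrophage and dendritic cell genes rose as a group in females (adjusted p = 0.00878; adjusted p = 0.761 with an estimated correlation), with 11 of 11 members positive, a median of 0.291, and 0 passing when adjusted over the list alone. Lyz2, which encodes lysozyme, differed by 0.81 (SE 0.29) and Cd74, an antigen presentation gene, by 0.72 (SE 0.25), or by 0.40 without female control 3. Genes of the female-biased list were lower relative to other genes (adjusted p = 1.15e-05; adjusted p = 0.0144 with an estimated correlation), 6 of 7 negative with a median of -0.2, and 0 passed when adjusted over the list alone. This call was the 1 list call of the 5 contrasts that held with an estimated correlation. Of 35 splits of the females, the real one included, 1 gave a camera adjusted p as small and 11 a median as large in size. Members of the list include the cytochrome gene Cyp2a4 at -1.45 (SE 0.73) and the steroid-metabolising Akr1c18 at -0.86 (SE 0.32). Female control 4, at 2.5 and 0.383 TPM, lay within the KlKl range for both. In every group replicates 1 and 2 bear names of series CFK, and 3 and 4 of series CFdk. In KlKl females Cyp2a4 stood at 5.51 and 6.01 TPM in the first series and 1.01 and 1.34 in the second. Akr1c18 stood at 1.31 and 1.15 against 0.2305 and 0.175. Name series was not separated from this fall. Cyp2a4 averaged 37.4 TPM in male controls and 11.2 in female controls, so it was not female-biased here. Genes of the steroid, prolactin and growth hormone receptor list were lower relative to other genes (adjusted p = 0.00232; adjusted p = 0.485 with an estimated correlation), with a median of -0.155. That list also holds genes that encode no receptor, such as Socs2 and the deiodinase gene Dio1. Within the list Socs2 differed by -0.36 and Prlr by -0.17, or by -0.17 and -0.042 without female control 3, and Prlr by -0.26 without female control 4. Cholesterol synthesis genes, with a median of -0.061, were lower relative to other genes (adjusted p = 0.00232; adjusted p = 0.761 with an estimated correlation). So were organic ion transporters (adjusted p = 0.00504; adjusted p = 0.761 with an estimated correlation), whose median of 0.008 was opposite in sign to the test and lay under the median of 0.105 over all tested genes. Slc22a7 differed by -1.28, and by -0.83 without female KlKl 4. Of these 3 lists 0 members passed when adjusted over the list alone, and the adjusted p of each member named was 0.727, or 0.745 for Prlr. Without female control 1 the calls ended for cholesterol synthesis (adjusted p = 0.246), organic ion transporters (0.239), the receptors and the macrophage genes (0.0557 each), and the macrophage call also without female control 4 (0.185) or female KlKl 4 (0.0524). By fry 0 lists passed in females.

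In females 1 gene passed and 376 of 8059 had an unadjusted p under 0.05, and limma voom on reads called 2, Kl and Crabp1, with 449 of 17648 at an unadjusted p under 0.05. The count was 0 with the libraries of the contrast alone and 2 without male KlKl 3 or female control 1.

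The interaction asked whether the effect of renal failure differs between the sexes. By limma 0 genes passed, 175 of 8059 had an unadjusted p under 0.05, and limma voom on reads called 0 with 427 of 17648 at an unadjusted p under 0.05. The gene nearest the threshold was Mgst1, with an effect larger by 1.13 in males (SE 0.20, adjusted p = 0.269). Slc7a12 differed by 1.39 (SE 0.28, adjusted p = 0.733) and Rarres2 by 1.98 (SE 0.50, adjusted p = 1.0). For Kl the difference of the effects was -0.68 (SE 0.33, adjusted p = 1.0) with a pseudocount of 1, 0.31 with a pseudocount of 0.1 and 0.81 on reads.

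10 lists passed the interaction test, all of them lost with an estimated correlation or by fry. Relative to other genes the male effect was more positive for tubule injury genes (adjusted p = 0.00427; adjusted p = 0.427 with an estimated correlation), with Spp1 at 0.65. It was also more positive for thick ascending limb genes (adjusted p = 0.00422; adjusted p = 0.472 with an estimated correlation), with Slc12a1 at 0.47, and for principal cell genes (adjusted p = 0.0119; adjusted p = 0.402 with an estimated correlation). Mineralisation genes had an adjusted p of 0.0202 and the steroid, prolactin and growth hormone receptor list one of 0.0227, each with an adjusted p of 0.402 with an estimated correlation. Female-biased genes went the same way (adjusted p = 0.00422; adjusted p = 0.217 with an estimated correlation), with Prlr at 0.85 and Cyp4a14 at 1.35, or 0.71 without male KlKl 3. Erythrocyte genes did too (adjusted p = 0.00422; adjusted p = 0.402 with an estimated correlation), with Hba-a1 at 2.51 (SE 1.10). The male effect was more negative for mitochondrially encoded transcripts (adjusted p = 1.11e-10; adjusted p = 0.402 with an estimated correlation), with mt-Nd4 at -0.71, or -0.24 without female control 3, and for male-biased genes (adjusted p = 5.99e-05; adjusted p = 0.402 with an estimated correlation), with Slco1a1 at -1.40 and Odc1 at -0.87, or -0.48 without male KlKl 3. Organic ion transporters were more negative (adjusted p = 0.00847; adjusted p = 0.635 with an estimated correlation), and without female control 3 and male KlKl 3 they pointed up with an adjusted p of 0.843. When adjusted over the list alone, 2 female-biased genes, 1 gene of the receptor list and 1 male-biased gene passed, and 0 of the other 7 lists. The gene count was 2 without male KlKl 3 and 2 without female control 4. Without male KlKl 3 the calls ended for injury (adjusted p = 0.103), male-biased (0.263), organic ion transporter (0.992), mineralisation (0.0944) and principal cell genes (0.0652). Without female control 1 they ended for thick ascending limb and receptor genes (0.103 each), mineralisation (0.0892) and principal cell genes (0.061). Without female control 4 they ended for organic ion transporter (0.0977), mineralisation (0.0978), principal cell (0.0518) and erythrocyte genes (0.057), and without male KlKl 4 for female-biased (0.0618), receptor (0.0618) and principal cell genes (0.0688). Others that ended a call were male KlKl 2 for mineralisation (0.0804) and erythrocyte genes (0.0597), male control 3 for mineralisation and receptors (0.0553 each), female control 3 for receptors (0.0896) and erythrocyte genes (0.0755), female KlKl 2 for transporters (0.0631) and female KlKl 3 for receptors (0.0759).

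The sexes were then compared within the controls. Male kidneys had more RNA of the cytochrome P450 gene Cyp4b1, 81.7 ± 14.3 against 2.25 ± 0.35 TPM, a log2 difference of 4.66 (SE 0.51, adjusted p = 7.4e-06, n = 4). The acyl-CoA synthetase gene Acsm3 was higher in males by 4.62 (SE 0.61, adjusted p = 3.21e-05), although the list fixed for female-biased genes holds it. The transporter gene Slc7a13 was higher by 4.59 (adjusted p = 2.68e-06) and the ethanol-oxidising Cyp2e1 by 3.82 (adjusted p = 1.19e-06). Females had more of the glucuronosyltransferase gene Ugt1a2, 24.7 ± 12.7 against 0.747 ± 0.3 TPM, a difference of -3.75 (SE 0.57, adjusted p = 9.66e-05).

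Further genes higher in control males were Ugt2b38 by 3.70, the carboxylesterase gene Ces1f by 3.08, the lactate dehydrogenase gene Ldhd by 2.99, the methyltransferase gene Inmt by 2.88, the urate transporter gene Slc22a12 by 2.79 and the acetyltransferase gene Nat8f2 by 2.77. Genes lower in males were Xist by -3.61, the mitochondrial tRNA gene mt-Ts1 by -3.02, Mir8097 by -2.37, the transcription factor genes Foxq1 by -1.88 and Cebpd by -1.69, the carbonyl reductase gene Cbr1 by -1.85, the fatty acid hydroxylase gene Cyp4a14 by -1.84, and the small RNAs Bc1 by -1.83 and Rny1 by -1.78. Rny1 stood at 29.8 TPM in female control 3, at no more than 2.67 in the other female controls and at no more than 1.32 in male controls. For so short a gene these lower values lie near the counting floor, and Rny1 met the naming rule's mean TPM only through female control 3. Its call ended without male control 2 (adjusted p = 0.0618). Bc1 stood at 2821 TPM in female control 3 against 327 to 589.4 in the other female controls. Without female control 3 Rny1 differed by -0.99 and Bc1 by -1.15. Kl was higher in control males by 1.41 (SE 0.23, adjusted p = 0.00018). Kl genotype was uneven here, since the wild-type controls were all male. The heterozygous males stood at 10.2 and 7.82 TPM, and the highest female control at 5.73. Ugt1a2, Cyp4a14 and the carboxylesterase genes belong to families that share reads, so their levels are uncertain.

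Male-biased genes were higher in control males (adjusted p = 0.000595; adjusted p = 0.376 with an estimated correlation), 10 of 10 members over all genes and when adjusted over the list alone, with a median of 1.918. Slco1a1 was higher by 2.46, Odc1 by 2.27 and Kap by 1.44. Fatty acid oxidation genes were higher (adjusted p = 0.00603; adjusted p = 0.551 with an estimated correlation), 16 of 20 over all genes and when adjusted over the list alone. The peroxisomal enzyme gene Ehhadh was higher by 1.90, the short-chain dehydrogenase gene Acads by 1.58, and Cpt1a, which admits fatty acids to mitochondria, by 1.00. Organic ion transporters (adjusted p = 0.00805; adjusted p = 0.551 with an estimated correlation) and proximal tubule markers (adjusted p = 0.0417; adjusted p = 0.551 with an estimated correlation) were higher, 13 of 16 and 15 of 21 members over all genes and when adjusted over the list alone. Examples are the anion transporter gene Slc22a6 at 2.27, the water channel gene Aqp1 at 1.29 and the transcription factor gene Hnf4a at 1.20. The proximal tubule call ended without male control 1 (adjusted p = 0.0539) or 4 (0.0504), male KlKl 1 (0.05003), or female control 1 (0.0509) or 3 (0.0707). The Kap call ended without male control 1 (0.068), 2 (0.0519), 3 (0.063) or 4 (0.0644), or female control 1 (0.073), 2 (0.056) or 4 (0.0972). In the vitamin D and phosphate axis the parathyroid hormone receptor gene Pth1r was higher by 0.92 and Vdr, the vitamin D receptor gene, by 0.64, and 9 of 14 members passed both over all genes and when adjusted over the list alone (list adjusted p = 0.0592).

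Tubule injury and extracellular matrix genes were lower in control males, each with an adjusted p of 0.000595 and an adjusted p of 0.376 with an estimated correlation. Of the injury genes 4 of 9 were lower, among them Spp1 by -1.17 and Vim by -0.59. Of the matrix genes 5 of 12 were lower and 1 higher, with Mgp at -1.35 and the collagen gene Col1a2 at -0.54. Interferon response genes were lower (adjusted p = 0.00151; adjusted p = 0.376 with an estimated correlation), 2 of 8, Gbp3 by -1.01 and Ifit1 by -0.63. Principal cell genes were lower (adjusted p = 0.00805; adjusted p = 0.376 with an estimated correlation), 2 of 7, and 2 of 5 mineralisation genes were lower. The mineralisation list had a median of -0.011 and was lower relative to other genes (adjusted p = 0.0402; adjusted p = 0.376 with an estimated correlation), whose median was 0.257. Genes of the receptor list, not all of which encode receptors, were lower (adjusted p = 0.0417; adjusted p = 0.397 with an estimated correlation), 3 of 6 lower and 2 higher, with the deiodinase gene Dio1 at -1.07 and the prolactin receptor gene Prlr at -0.99. Female-biased genes were lower (adjusted p = 0.0496; adjusted p = 0.376 with an estimated correlation), 3 of 7 lower and 2 higher, with Slc7a12 at -1.01. These counts were the same when adjusted over the list alone. The mineralisation call ended without female control 1 (adjusted p = 0.0615). The receptor call ended without male control 1 (0.0539), male KlKl 1 (0.05003), male KlKl 3 (0.0575), female control 1 (0.0705) or female control 3 (0.0707). The female-biased call ended without male control 1 (0.054) or 4 (0.0585), male KlKl 1 (0.0538), 2 (0.0514) or 3 (0.125), female control 1 (0.0705) or 3 (0.0811), or female KlKl 2 (0.05036), 3 (0.0501) or 4 (0.0526). After the stricter filter it pointed up (0.891). By fry the injury and mineralisation lists were kept as lower in control males, and the matrix, interferon, principal cell, receptor and female-biased lists were not.

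In total 4236 of 8059 genes (52.6%) differed between control sexes, 3567 higher and 669 lower in males. The median difference over all tested genes was 0.257, and after median-ratio scaling, which takes it to -0.006, 1978 genes were higher and 1929 lower. Limma voom on reads called 3644 higher and 3297 lower of 17648. With heterozygous controls alone, which leaves out the wild-type males and so has fewer libraries, 2275 genes passed. The uneven Kl genotype of the control sexes is thus not separated from sex in the full count. Library numbers 17 to 24 occur once in each sex, so that the sexes may have been sequenced separately, and such a run cannot be told apart from sex.

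**Figure D2:**
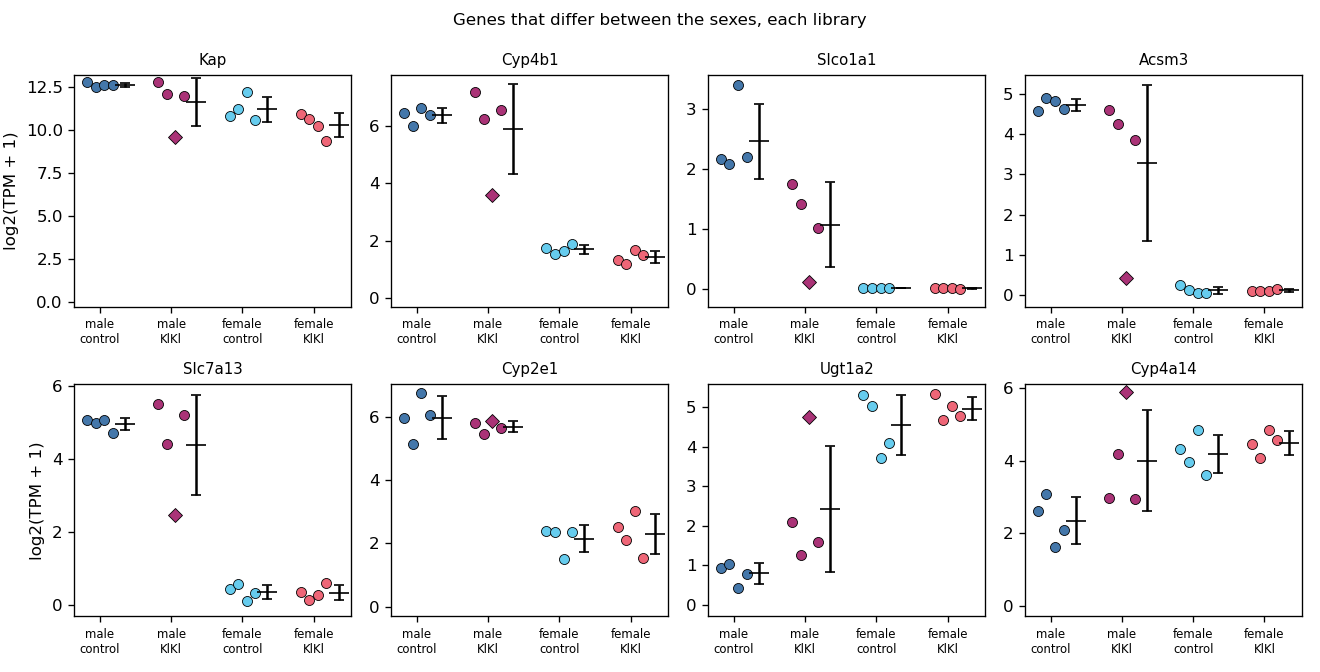
Levels of 8 genes that differ between control sexes, as log2(TPM + 1) in each of the 16 libraries, by group, with the mean and SD of each group of 4 in black and male KlKl 3 as a diamond. Acsm3 stood at 0.328 TPM in male KlKl 3 and at 13.5 to 23.3 TPM in the other KlKl males, while Cyp2e1 stood at 56.7 TPM in that library and at 42.4 to 55.2 TPM in the others.

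The sexes were also compared within KlKl animals. Cyp4b1 was higher in males by 4.45 (SE 0.51, adjusted p = 1.23e-05), Slc7a13 by 4.05 (SE 0.44, adjusted p = 8.56e-06), Cyp2e1 by 3.39 (SE 0.33, adjusted p = 3.32e-06) and Acsm3 by 3.18 (SE 0.61, adjusted p = 0.000569). Nat8f2 was higher by 2.86, Ces1f by 2.66, Ldhd by 2.55 and the carboxylesterase gene Ces2c by 2.45. The globin genes Hbb-bs and Hba-a2 were higher by 2.49 (SE 0.83, adjusted p = 0.0195) and 2.45 (SE 0.85, adjusted p = 0.023). Their calls ended without male KlKl 1 (adjusted p = 0.0545 and 0.0552), male KlKl 2 (0.0637 and 0.0723) or female KlKl 2 (0.0642 and 0.0678). Genes lower in KlKl males were Xist by -3.45, mt-Ts1 by -3.44, Cebpd by -1.20, Cbr1 by -1.19, Mgp by -0.97, Hoxb4 and the glutathione transferase gene Gsta2 by -0.87 each, mt-Nd3 by -0.84, Spp2 by -0.78 and Tmsb10 by -0.75.

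Cyp24a1 and Cyp27b1 were higher in KlKl males than in KlKl females by 1.91 (SE 0.59, adjusted p = 0.0128) and 1.41 (SE 0.31, adjusted p = 0.00159), and Kl by 0.73 (SE 0.23, adjusted p = 0.015). Without male KlKl 1 the calls of Cyp24a1 and Kl ended (adjusted p = 0.0512 and 0.0567). The antioxidant gene Nqo1 was higher by 1.07 (SE 0.15, adjusted p = 4.44e-05). Prlr, at -0.14 (adjusted p = 0.499), did not pass here, and differed by -0.075 without male KlKl 1, -0.022 without male KlKl 2 and -0.30 without male KlKl 3.

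Male-biased genes were higher in KlKl males (adjusted p = 0.0115; adjusted p = 0.586 with an estimated correlation), again 10 of 10 over all genes and when adjusted over the list alone, with a median of 1.367. Of 35 splits of the KlKl libraries, the real one included, 16 gave a camera adjusted p as small and 1 a median as large. Slco1a1 was higher by 1.06, Odc1 by 1.40 and Kap by 1.33, whose call ended without 12 of the 16 libraries in turn, with an adjusted p of up to 0.168 without male KlKl 1. Kap was higher by 2.01 without male KlKl 3. Fatty acid oxidation genes were higher (adjusted p = 0.0115; adjusted p = 0.586 with an estimated correlation), 16 of 20, with Ehhadh at 1.59. Matrix genes were lower (adjusted p = 9.8e-05; adjusted p = 0.586 with an estimated correlation), 3 of 12 lower and 1 higher. Mitochondrially encoded transcripts, with a median of -0.072, were lower relative to other genes (adjusted p = 9.8e-05; adjusted p = 0.586 with an estimated correlation), 4 of 13, or 3 when adjusted over the list alone. Interferon response genes were lower (adjusted p = 0.00051; adjusted p = 0.586 with an estimated correlation), 2 of 8, or 0 when adjusted over the list alone. Injury genes were lower relative to other genes (adjusted p = 0.0113; adjusted p = 0.586 with an estimated correlation), although 1 of 9 was higher and 0 lower. Organic ion transporters, with Slc22a6 at 1.93, had an adjusted p of 0.0507 with 13 of 16 members higher. After quantile normalization the mitochondrial list pointed up (adjusted p = 0.945). By fry the male-biased and fatty acid oxidation lists were kept, and 0 of the 4 called lower.

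In total 4406 of 8059 genes (54.7%) differed between KlKl sexes, 4106 higher and 300 lower in males, and 1524 and 1393 after median-ratio scaling. The median difference over all tested genes was 0.332, and limma voom on reads called 2614 higher and 2372 lower. A sequencing run for each sex remains confounded with sex here too.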

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

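The scaling, gene copy, male KlKl 3, proximal tubule and sex pattern tests were chosen only after the results were seen.

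Of 308 groups of 4 values, from 77 genes looked at in each library, 23 held a library far from the other 3. Chance gives about 15.4 for independent genes chosen beforehand. Some of these genes were chosen after their values were seen and genes vary together, so the 2 numbers make no test. Male KlKl 3 accounted for 8 of the 23 groups. It was low for Ces1f (3.69 TPM), Ces2c (8.67), Cyp24a1 (4.48), Nat8f2 (2.22), Ugt2b38 (0.968) and Ifit1 (0.504), and high for Aqp1 (116.7) and B430119L08Rik (4.12). Female control 3 was low for mt-Nd2 (2437 TPM), mt-Nd4 (1817) and Cyp2e1 (1.84), and high for Rny1 (29.8) and Trib1 (1.99), and its age of 57 days stood apart from 47 to 48 days. Ribosomal RNA took 15.2% of its TPM, against 3.32% to 6.13% in the other female controls. Male control 3 was low for Gbp3 (0.349 TPM) and Mir8097 (0.229) and high for Slco1a1 (9.62). The others were Cbr1 in male control 4 (8.06 TPM), Pth1r in male KlKl 4 (15.2), Cyp2a4 in female control 4 (2.5), Hba-a2 (1.49) and Nqo1 (2.41) in female control 1, Lyz2 in female KlKl 1 (4.57) and Ddx3y in female KlKl 2 (0.00468). The Ddx3y value lies near the counting floor.

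Between the sexes, 10 lists had a renal failure effect that differed by camera. The adjusted p values were 0.00427 for tubule injury, 0.0202 for mineralisation, 1.11e-10 for mitochondrially encoded transcripts, 0.00847 for organic ion transporters, 5.99e-05 for male-biased genes, 0.00422 each for female-biased, thick ascending limb and erythrocyte genes, 0.0227 for steroid, prolactin and growth hormone receptors and 0.0119 for principal cell genes. With an estimated correlation 0 of these 10 passed (adjusted p of 0.217 to 0.635), and by fry 0 passed. Of 100 permutations of residuals, the real arrangement included, 16 gave 10 or more list calls and the highest other gave 12, so chance is not excluded for their number.

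Counts of genes and of lists were set against other splits of the libraries. In males 1 of 35 splits, the real one, gave 8 genes or more and the highest other gave 3. A count this large is thus rare among the splits, but it holds Kl, the mutated gene, and 35 splits allow no smaller share. Chance is not excluded for the other genes of that count. For lists, 24 of 35 splits gave 8 list calls or more, with up to 15. Among the male list calls, a camera adjusted p as small came in 9 splits for proximal tubule markers and in 1 to 3 for the others. A median as large came in 1 to 4 for the injury, mineralisation, mitochondrial and thick ascending limb lists. It came in 7 for proximal tubule, 11 for male-biased, 21 for transporter and 24 for cholesterol genes. In females 7 of 35 splits gave at least 1 gene, so chance is not excluded, and 9 of 35 gave at least 5 list calls, with up to 10. The female split of control 1 with KlKl 1, 3 and 4 called 69 genes, which points to a structure of these libraries. That split follows genotype for 6 of the 8 libraries, and what drives it was not tested. For the sexes, 1 of 35 splits gave as many genes as the 4236 in controls and 1 of 35 as the 4406 in KlKl, with other splits at no more than 1 and 2, so chance is excluded. List calls were as many in 4 of 35 splits for the 11 in controls, with up to 13, and in 25 of 35 for the 6 in KlKl, with up to 13. The interaction count of 0 is met by all 100 permutations.

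The first pattern is that on the deposited scale about as many genes differed between the sexes as did not, 52.6% in controls and 54.7% in KlKl. On reads the shares were smaller, 6941 of 17648 genes in controls and 4986 in KlKl. After median-ratio scaling 3907 genes passed in controls against 4236. A few abundant genes taking another share of the TPM therefore do not account for the size of that count. The directions moved, from 3567 higher and 669 lower in males to nearly even, so for which genes passed this explanation stays open. In KlKl animals 2917 passed (36.2%) against 4406, so there it stays open for the count too. With all libraries thinned to the depth of the shallowest, 6103 genes passed in controls in the fit on reads, against 6941 on all reads. Deeper male libraries therefore do not account for the count on reads. The count on the deposited scale was not thinned. Also open is a run for each sex that handled gene copies differently. In the fit on reads, pseudogenes lay 0.582 above protein-coding genes in the median log2 sex difference of controls, which such a run could give. The value in KlKl animals was 0.33. Pseudogenes as a whole held a smaller share of reads in males, 6.21% to 7.47% against 8.75% to 9.92% in females. The TPM ratio of mt-Co1 to its copy Gm29216 was 1.72 to 4.36 in males and 0.252 to 0.996 in females. Sex itself stays open as well, since 50.9% of protein-coding genes passed, and the design does not separate it from a run.

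The second pattern is the lower male-biased list in KlKl males. Of 35 splits of the males, the real one included, 11 gave a list median as large in size and 2 a camera adjusted p as small. Chance is therefore not excluded for the fall of this list. Scaling does not account for the fall, since the list median was -0.548 after median-ratio scaling. An even loss of proximal tubule RNA is argued against as the whole cause, since its 21 markers had a median of -0.041 on those values (SD 0.292), but they ranged from -0.857 to 0.237, so a loss in part of the markers stays open. Male KlKl 3 carried most of the size: without it the median was -0.043. A shift of male kidneys towards the female pattern, as a hypothesis, is left open: with male controls divided between both contrasts, the male effect correlated across genes with the sex difference at a mean of -0.266 over 6 divisions, and at -0.167 without male KlKl 3, against -0.376 with the controls shared. Against the sex difference of all libraries the correlation was -0.283, and 10 of 35 splits of the males gave one as large, with up to 0.412, so chance is not excluded and genes are not independent replicates.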

How the results depend on the processing

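Chosen after seeing the data were the read-based fit, scaling on nuclear protein-coding genes, the pair of female control 3 and male KlKl 3 left out together, age with median-ratio scaling or without female control 3, weights with median-ratio scaling, and every value for the mean of both sexes. For the single genes followed, 4695 of 4999 comparisons with an alternative kept direction and side of the threshold, 222 lost and 79 gained the call, and 3 reversed. For lists 1138 of 1352 did, 208 lost the call and 6 reversed. Except where a filter, a threshold or fewer libraries changed what was tested, the cause was not tested.

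The 8 male renal failure genes became 3 with a pseudocount of 0.1, 5 with no filter, 2 with the stricter filter, 2 with median-ratio scaling or quantile normalization (0 higher), 3 without mitochondrial and top 10 genes, 249 with array weights, 909 with the age covariate, 1 with heterozygous controls only, 2 at an adjusted p under 0.01, 3 with only the libraries of the contrast, 5 on reads with voom, 3 scaled on nuclear protein-coding genes, 25 without female control 3 and male KlKl 3, 1 with the age covariate and median-ratio scaling, and 1674 with the age covariate without female control 3. Leaving out 1 library at a time gave 2 to 17.

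The female count of 1 became 3 with no filter, 0 with the stricter filter or only the libraries of the contrast, 9 with array weights, 2 on reads with voom or without female control 3 and male KlKl 3, and 776 with array weights and median-ratio scaling, and 1 to 2 leaving out 1 library. The interaction count of 0 became 8 with array weights, 7 with array weights and median-ratio scaling, 1 without female control 3 and male KlKl 3, and 0 to 2 leaving out 1 library. The mean of both sexes, 3, became 8 with no filter, 536 with array weights, 134 with array weights and median-ratio scaling, 1407 with the age covariate, 1 with the age covariate and median-ratio scaling, 1156 with the age covariate without female control 3, 15 without female control 3 and male KlKl 3, and 2 to 11 leaving out 1 library.

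The 4236 genes of the control sexes became 6442 with no filter, 1393 with the stricter filter, 2275 with heterozygous controls only, 823 at an absolute log2 fold change of 1 or more and 6941 on reads with voom. The 4406 of the KlKl sexes became 7845 with no filter, 1226 with the stricter filter, 2917 with median-ratio scaling, 691 at an absolute log2 fold change of 1 or more and 2883 scaled on nuclear protein-coding genes (1836 higher, 1047 lower). The 40 list calls became 61 with no filter, 22 with the stricter filter and 1 with an estimated correlation. The 40 were 17 higher and 23 lower, while fry made 42 calls, 38 higher and 4 lower, and shared 11 with them. On the deposited scale the median difference over all tested genes was positive in each contrast, which favours higher calls by fry.

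The Kl interaction of -0.68 reversed to 0.31 with a pseudocount of 0.1, 0.81 on reads with voom and 0.21 with array weights and median-ratio scaling. Lists that reversed, with adjusted p, were proximal tubule in males by fry (0.407), organic ion transporters in the interaction with no filter (0.909), on reads with voom (0.278) and without female control 3 and male KlKl 3 (0.843), female-biased genes of control sexes with the stricter filter (0.891) and mitochondrial transcripts of KlKl sexes with quantile normalization (0.945).

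Animals with the same number had correlations of -0.222 to 0.219. Between male controls and male KlKl 2 of 4 pairs were over 0.1 and 2 correlated best with their own number, and between the female groups 2 of 4 were over 0.1 and 0 did. In no pair of groups were all 4 over 0.1 or all 4 best with their own number, so the numbers were not taken as pairs. With the replicate block 6 genes passed in males and 41 list calls were made. The test for deposited counts, chosen before the data were seen, was not run because the deposited values are TPM. Limma voom on recovered reads was added after they were seen. Array weights, no trend and robust fits gave no list values.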

Other observations

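The neighbours test was chosen before its result was seen, and the mean of both sexes and the values of male KlKl 3 were chosen after seeing the data.

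Crabp1, which encodes a binding protein for retinoic acid, passed in both sexes on recovered reads and was too low in TPM for the main test. It had 1 to 3 reads in male controls and 0 to 7 in female controls, against 19 to 68 in KlKl males and 59 to 91 in KlKl females. The log2 difference by limma voom was 4.28 in males (adjusted p = 0.0491) and 5.44 in females (adjusted p = 0.00729). Osbp2, a lipid-binding protein gene, was lower in KlKl males by -1.07 (adjusted p = 0.00663), with 129 to 210 reads against 294 to 526. Both were chosen after their values were seen.

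As a mean of both sexes, 3 of 8059 genes passed in renal failure by limma: Kl at -2.21 (adjusted p = 3.85e-06), Serpina1a at 1.80 (adjusted p = 0.00702) and the noncoding gene B430119L08Rik at 0.83 (adjusted p = 0.0445). Serpina1a and B430119L08Rik lie close together on chromosome 12, at positions 103819848 to 103829822 and 103862156 to 103865044. Limma voom on reads called 4: Kl, Serpina1a, Crabp1 and Anxa13, the last at -1.14 (adjusted p = 0.0231). Of 100 reassignments of genotype within each sex, the real one included, 2 gave 3 genes or more and the highest other gave 5, and 9 gave the 10 list calls or more, with up to 13. That count holds Kl, the mutated gene, and another reassignment gave 5 genes, so chance is not excluded for Serpina1a and B430119L08Rik. Nor is it for the list calls, of which 0 held with an estimated correlation. The gene count was 10 without male KlKl 3 and 11 without male KlKl 4, and the B430119L08Rik call ended without 10 of the 16 libraries.

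Male KlKl 3 lay apart from the other KlKl males in several genes that differ between the sexes. Xist and Ddx3y in it were those of a male. Acsm3 was at 0.328 TPM against 13.5 to 23.3 in the other KlKl males, Slco1a1 at 0.0835 against 1.02 to 2.37, Kap at 761 against 4038 to 7074 and Cyp4b1 at 11.2 against 74.3 to 142. Ugt1a2 was at 26.0 TPM against 1.38 to 3.27, and Cyp4a14 at 58.4 against 6.71 to 17.2, where the highest female libraries stood at 39.3 and 28.1. The Cyp4b1 and Slco1a1 levels lay between the sexes, with females at no more than 2.68 and 0.0155 TPM. Cyp2e1, at 56.7 TPM, stayed with the males. Cyp27b1 was at 13.9 TPM against 3.59 to 6.08, and Kl at 0.258 against 0.881 to 1.49.

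The third pattern is that Kl was lower in both sexes while few other genes passed, and the hypothesis that genes inherited with the mutation on chromosome 5 may differ too was tested. Of 105 genes within 10 Mb of Kl, 6.67% had an unadjusted p under 0.05 for the mean effect on reads, against 5.92% elsewhere. That share lay at percentile 58.9 of 604 windows of as many neighbouring genes, between the bounds set for and against, so the hypothesis stays open. The smallest adjusted p among these genes was 0.0737.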
